A study of Mus musculus with 6 samples.

How the data were processed

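Soleus muscle of male mice aged 39 to 41 weeks was profiled on Affymetrix whole-transcript arrays. Per the labels' protocols, muscles from both legs were flash frozen, total RNA was column purified with DNase treatment, and 100 ng was converted to biotinylated cDNA. There were 3 Control mice, littermates labelled wild type, and 3 cKO mice, in which Mbtps1 was deleted with a Dmp1-driven Cre recombinase. Each mouse gave 1 array, and groups and replicate numbers were taken from the sample titles. The number of arrays limits the precision of every value.

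The deposited value table held 1 column per array, and its values were read as log2 signals. The log base, background correction, summarisation, normalization between arrays, software and genome build were not given in the sources used here. The log2 reading rested on the range of the values, which ran from 1.92 to 19.93. The table had 72688 features, of which 6732 with purely numeric identifiers held no value on any array and were left out. The other 65956 had a value on all 6 arrays. Array medians were 4.13, 4.03 and 4.08 for Control 1 to 3 and 4.37, 4.03 and 4.00 for cKO 1 to 3. On each array 41 to 55 features shared the highest value to within 0.01 log2 units, which marks a ceiling of the scale. A feature at the ceiling on all arrays of a group was treated as saturated, and no fold is given for it as a single gene. Saturated features stayed in the list means and tests, except in the alternative that removed them. There were 40 such features, 20 of them with 1 gene symbol.

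Gene symbols came from the platform annotation, with 30604 features carrying 1 symbol, 2146 carrying several and 33206 unnamed here. Of the features with 1 symbol, 22818 were matched by Entrez identifier to a RefSeq gene table on assembly GRCm38.p6, and 827 symbols were updated through that match. The table served only for names and for which genes neighbour each other, and no coordinates are given because no build was named for the deposited values. No gene was named from a feature with several symbols. Where a gene had several features, the one with the highest mean over the 6 arrays was used.

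Features were tested when they lay above the median of their own array on at least 3 arrays, which left 33334 features and 18334 genes. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, on the log2 values as deposited and without a block. P-values were adjusted by the Benjamini-Hochberg method over all features tested. A second count took features with an unadjusted p under 0.01 and a fold of at least 1.5. Adjusted p-values of single genes are limma's, and those of gene lists come from limma's camera with a preset inter-gene correlation of 0.01, adjusted over 30 lists. Camera sets a list against all other genes measured. Fry, also in limma, tests whether a list's genes move on balance one way and does not compare them with other genes. Errors of list means are standard errors of the difference between groups over arrays. Exact permutation tests of 3 against 3 arrays are two-sided and cannot give a p below 0.1. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

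The design, the tests, the 30 gene lists, the rule for named genes and all alternatives except 2 were fixed before the data were examined. The rule named Mbtps1 and a fixed set of 16 muscle genes. It also took, in each direction, the 12 largest folds past an adjusted p of 0.05 with full separation of the groups. Where fewer than 8 passed, the set was filled to 8 by the smallest unadjusted p among genes with a fold of at least 1.5 and full separation, leaving out predicted genes, receptors of smell, small RNAs and antigen receptor segments. From each list past the threshold it took the 4 members with the smallest p, and from each other list 2. Genes named outside the rule were chosen after their values were seen. These are Dbp, Per1, Bhlhe40, Bhlhe41, Clock, Comp, Col12a1, Scx, Hspa1a, Fos, Egr1, Chrnb1, Chrna1 and Dmp1, and those listed in the closing section.

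The alternatives were quantile normalization, centring on array medians, no filter, a filter at the 75th percentile, eBayes without a trend or with robust settings, array weights, the replicate number or the range of mouse numbers as a block, each array left out, single-symbol features only, an adjusted p of 0.10, a fold of 2, an estimated inter-gene correlation, fry, and the mean of all features of a gene. Removal of saturated features, and quantile normalization together with the number range as a block, were added after the values were seen. The count of list members past 0.05 adjusted over the list alone was not among the results fixed at the start, and it was run under the same alternatives.

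The fit was tested on simulated data with the spread of these arrays, over 33334 features of which 200 were changed. It recovered 16% of 2-fold and 83% of 4-fold changes, with the direction correct in 100% of those recovered, and called 6 unchanged features. A list shifted by 0.5 log2 units was called and 0 of the other lists were. In splits of the real arrays that mixed the genotypes, the same list test called 5 to 13 of 30 lists. The simulation therefore does not give the rate of false list calls in these data. Its recovery rates hold for 200 changed features and need not hold here. On the real arrays Angptl7 and Sln, with folds of 4.59 and 4.93 and full separation, had a limma adjusted p of 0.999.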

Results

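Gene expression was measured in the soleus, a calf muscle rich in slow fibres, of 3 Control mice and 3 cKO mice. In the cKO mice a Cre recombinase driven by regulatory sequence of Dmp1, a gene of bone-embedded osteocytes, deleted Mbtps1. The mice were littermates by the series title and carried numbers that fell in 2 ranges. Mice 715, 716 and 733 (Control 1, Control 2 and cKO 1) had low numbers, and mice 776, 779 and 780 (Control 3, cKO 2 and cKO 3) had high numbers. The labels did not say whether a range marks a litter or a processing batch. Over all features tested, the arrays correlated between 0.970 and 0.995. The first principal component held 43.9% of the variance and separated the number ranges, with the low-numbered arrays at -24.6, -75.2 and -21.3 and the high-numbered arrays at 56.5, 32.7 and 32.0. The second held 22.3% and set cKO 1 apart, at -67.7 against -4.17 to 27.8 for the other arrays, and cKO 1 had the lowest array weight in limma (0.254, against 0.589 to 4.01). The median difference over all features tested (cKO minus Control) was 0.07 log2 units as deposited and -0.0038 after quantile normalization. Counts of higher genes are on the deposited scale unless stated. For this reason the differences of lists that passed are also given within the low and within the high numbers, where 1 array of one genotype faces 2 of the other. Of the 22 lists that did not pass, 15 kept the sign of their mean in both ranges, and the range values are given for the 7 that did not.

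Mbtps1 encodes site-1 protease, which cleaves membrane-bound transcription factors such as the sterol-responsive SREBPs and ATF6 in the Golgi. Its log2 signal was 7.39, 7.05 and 7.24 in Control 1 to 3 and 7.77, 7.44 and 7.11 in cKO 1 to 3. The difference of 0.21 log2 units (SE 0.21) did not pass (limma adjusted p = 0.999), and was 0.55 within the low and 0.03 within the high numbers. It was 0.07 after quantile normalization, 0.09 with array weights, 0.13 without Control 2, 0.05 without cKO 1 and 0.38 without cKO 3. The part of Mbtps1 that the feature covers, relative to the deleted part, was not given in the sources used here. The Cre was driven by regulatory sequence of an osteocyte gene, so whole soleus need not show a loss. For both reasons the level of Mbtps1 does not check the labels. The SREBP target list of cholesterol synthesis, with 12 of 17 measured genes higher, differed by 0.10 log2 units (SE 0.10, limma camera adjusted p = 0.367), and the endoplasmic reticulum stress and ATF6 list by 0.19 (SE 0.12, adjusted p = 0.132) with 18 of 24 higher. Neither list passed. The cholesterol difference was 0.31 within the low and -0.03 within the high numbers, 0.0042 after quantile normalization, where 8 of 17 were higher, and 0.0037 without cKO 1. The stress list differed by 0.10 after quantile normalization and 0.11 without cKO 1, and it passed without cKO 2 (adjusted p = 0.0205, in a range of 0.0205 to 0.830 over the alternatives).

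The comparison of cKO with Control asked how muscle differs when Mbtps1 is deleted in Dmp1-expressing cells. By camera with its preset correlation, 5 lists were higher in cKO soleus relative to all other genes. These were tendon genes, clock genes, genes of myogenic differentiation, genes of the neuromuscular junction and denervation, and immediate early and heat shock genes. Clock genes were higher only as a list mean, with 14 members higher and 4 lower, Arntl and Clock among the lower. Genes of oxidative phosphorylation, the citric acid cycle and fatty acid oxidation were lower relative to all other genes by the same test. Their mean differences were -0.10, -0.16 and -0.04 log2 units (SE 0.13, 0.10 and 0.17). Together the higher and lower lists made 8 of 30 past an adjusted p of 0.05 in limma's camera with its preset correlation of 0.01. The estimated correlations of the 8 lists ran from 0.03 for clock genes to 0.41 for tendon genes. In splits of the arrays that mixed the genotypes, the same test called 5 to 13 lists. With an estimated correlation camera called 0 of the 30 lists and fry called 0, with 1 and 7 lists at an unadjusted p under 0.05, against 12 for the preset correlation. Of 33334 features tested with limma, 0 passed an adjusted p of 0.05, and 1501 had an unadjusted p under 0.05, where chance alone gives 1666.7. With the number range in the model, 2004 features had an unadjusted p under 0.05 for genotype. The 3 cKO arrays lay wholly above or below the 3 Control arrays for 11.0% of features, where chance gives 10%. At an unadjusted p under 0.01 and a fold of at least 1.5 there were 223 features, 192 higher and 31 lower in cKO. That split was 112 and 59 after quantile normalization, and 97 and 33 after centring on array medians. With quantile normalization and the number range as a block together it was 136 and 134, and without Control 1 it was 70 and 70. Without Control 3, 14 features passed the adjusted threshold (3 higher, 11 lower), and the second count was 944. It was 140 without Control 1, 132 without cKO 2 and 94 without cKO 3.

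**Figure D1:**
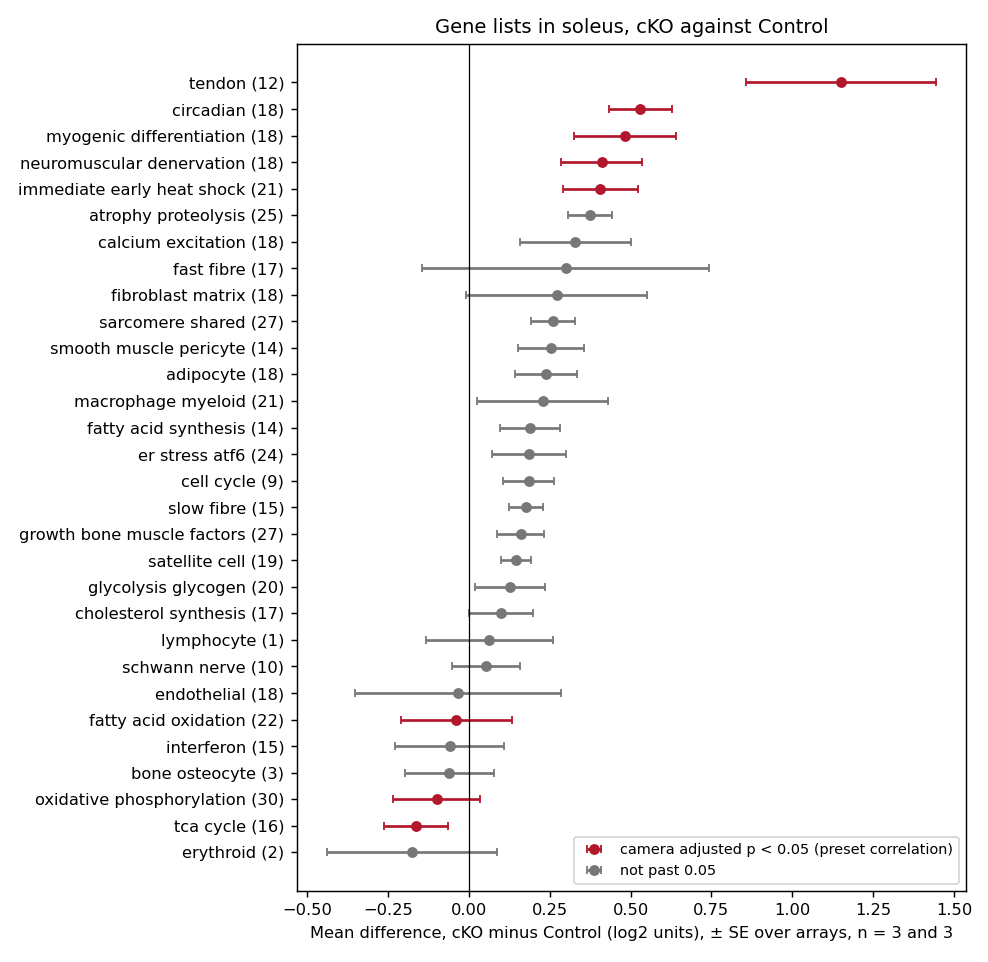
Mean difference between cKO and Control for each of 30 gene lists, in log2 units, with the number of measured genes in brackets and bars of 1 standard error over 3 arrays per group. Red points mark the 8 lists past an adjusted p of 0.05 in limma's camera with the preset correlation, from 1.15 for tendon to -0.16 for the citric acid cycle, none of which passed with an estimated correlation.

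Genes of myogenic differentiation were higher as a group in cKO soleus. The list mean was 8.51 ± 0.25 (SD, n = 3) in Control and 8.99 ± 0.10 (SD, n = 3) in cKO, a difference of 0.48 log2 units (SE 0.16), and 16 of 18 measured members were higher (13 after quantile normalization). The myogenic regulators Myf6 and Myod1 differed by 1.07 (SE 0.32) and 0.59 (SE 0.17), each with all cKO arrays above all Control arrays, and Myog by 0.39 (SE 0.25). Embryonic myosin Myh3 differed by 0.996 (SE 0.33), neonatal myosin Myh8 by 0.28 (SE 0.20) and the myosin-binding protein gene Mybph by 0.45 (SE 0.13). The list passed camera (adjusted p = 0.000693), but not with an estimated correlation (adjusted p = 0.741, the highest of 19 alternatives that began at 6.60e-07). By limma, 0 of the 18 members passed when adjusted over the list alone and 0 over all features, while 7 had an unadjusted p under 0.05. The difference was 0.68 within the low mouse numbers and 0.17 within the high ones, and 0.32 with quantile normalization and the range block together. Tendon markers, of another cell type, moved with this list. Its array means were 8.39, 8.34 and 8.80 in Control 1 to 3 and 9.04, 8.88 and 9.06 in cKO 1 to 3, against 6.17, 6.24 and 6.91, and 7.35, 7.51 and 7.92, for tendon.

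Genes of the neuromuscular junction and the response to denervation also rose, by a mean of 0.41 log2 units (SE 0.12), with 15 of 18 members higher (13 after quantile normalization). Musk, the receptor kinase that organises the muscle side of the synapse, differed by 1.39 (SE 0.34), and Dok7, its activator, by 0.41 (SE 0.12). The transcription factor Runx1 differed by 0.79 (SE 0.21), the adhesion molecule Ncam1 by 0.85 (SE 0.28), and the acetylcholine receptor subunits Chrnb1 and Chrna1 by 0.98 (SE 0.35) and 0.68 (SE 0.29). Chrna1, Ncam1 and Myog belonged to the myogenic list too. The list passed camera (adjusted p = 0.000745) and did not with an estimated correlation (adjusted p = 0.624, the highest of 19 alternatives from 3.34e-05) or with the number range as a block, where the mean was 0.34 and the adjusted p 0.0904. Over the list alone 0 members passed in limma, with 5 at an unadjusted p under 0.05, and the mean differences were 0.42 within the low and 0.26 within the high numbers, and 0.23 with quantile normalization and the range block together (adjusted p = 0.0948). The array means, 6.68, 6.72 and 6.997 in Control 1 to 3 and 7.12, 7.15 and 7.37 in cKO 1 to 3, had the same order as those of the tendon list.

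Stem cell and fibre type genes did not pass as groups. Satellite cell genes differed by 0.15 log2 units (SE 0.05, camera adjusted p = 0.172), with 14 of 19 higher, and by 0.05 after quantile normalization (12 of 19) and 0.09 after median centring. Pax7, the stem cell transcription factor, was at 4.81 ± 0.07 (SD, n = 3) in Control and 4.91 ± 0.05 (SD, n = 3) in cKO, and Myf5, Itga7 and Met differed by 0.31 (SE 0.16), 0.69 (SE 0.265) and 0.45 (SE 0.20). Slow fibre genes differed by 0.18 (SE 0.05, adjusted p = 0.434), with 12 of 15 higher. The stretch-responsive genes Csrp3 and Ankrd2 differed by 0.90 (SE 0.20) and 0.56 (SE 0.19), while slow myosin Myh7 differed by 0.05 (SE 0.15), a sign that turned on centring to array medians. Fast fibre genes had a median difference of 0.01, which was the value of Myh2, a feature at the ceiling. Their mean difference was 0.30 (SE 0.44), and camera's direction was down (adjusted p = 0.434). Their mean rested largely on cKO 2, where fast myosin Myh4 stood at 16.9 against 11.7 to 13.7 on the other arrays and Actn3 at 15.7 against 7.97 to 11.5. Control 1 contributed as well, with the lowest list mean, at 14.9 against 15.6 in Control 2 and in Control 3. Without cKO 2 the list mean was -0.06 and passed camera in the downward direction (adjusted p = 0.0104, within a range of 0.0104 to 0.893 over the alternatives). Myh2 was saturated in both groups, and Myh1 differed by 0.02 (SE 0.22) with a sign that turned under quantile normalization and median centring. Myh7, at 19.2 to 19.4, and Myh1, at 19.1 to 19.7, lay near the array maxima of 19.765 to 19.932. The ceiling of the scale could therefore hide a difference in either gene. In these lists limma passed 0 members over the list alone, with 1, 3 and 0 at an unadjusted p under 0.05 for satellite cell, slow and fast genes.

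Genes of the circadian clock differed in opposite directions between cKO and Control. Over 18 measured members the mean rose by 0.53 log2 units (SE 0.10), with 14 higher and 4 lower. Arntl, the activator at the centre of the clock, fell by 1.73 (SE 0.25) and its partner Clock by 0.58 (SE 0.19). The repressors Per2, Per1 and Cry2 rose by 1.23 (SE 0.18), 1.38 (SE 0.40) and 0.87 (SE 0.17). Usp2 and Bhlhe41 rose by 1.23 (SE 0.30) and 1.26 (SE 0.35), and Dbp, a transcription factor driven by the clock, by 1.90 (SE 0.47). With Bhlhe40, these were the 9 genes past 0.05 adjusted over the list alone in limma, against 0 over all features, and all 9 had full separation of the groups. The list passed camera (adjusted p = 0.00261), and not with an estimated correlation (adjusted p = 0.624, the highest of 19 alternatives from 0.000129). The mean difference was 0.64 within the low and 0.34 within the high mouse numbers. Array means were 8.01, 8.02 and 8.30 in Control 1 to 3 and 8.65, 8.60 and 8.67 in cKO 1 to 3, with Control 3 the highest Control array here as in the tendon list. The count of 9 was 3, 5 and 13 without Control 1, 2 and 3, and 4, 2 and 2 without cKO 1, 2 and 3, where 5 arrays were tested. It was 14 with array weights, and 5 with quantile normalization and the number range as a block together.

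Tendon genes rose in cKO soleus, with 12 of 12 measured members higher (11 after quantile normalization) and a mean difference of 1.15 log2 units (SE 0.29). Per-array list means were 6.17, 6.24 and 6.91 in Control 1 to 3 and 7.35, 7.51 and 7.92 in cKO 1 to 3. In limma 6 members passed when adjusted over the list alone and 0 over all features. These were Angptl7 at 2.20 (SE 0.35), the matrix proteins Chad at 1.97 (SE 0.36), Fmod at 1.68 (SE 0.39) and Comp at 1.06 (SE 0.34), the tendon cell membrane protein Tnmd at 1.27 (SE 0.32) and the collagen Col12a1 at 0.77 (SE 0.24). Scx, a transcription factor of tendon cells, differed by 0.07 (SE 0.15). The list passed camera (adjusted p = 2.29e-08), and not with an estimated correlation (adjusted p = 0.624, the highest of 19 alternatives from 2.90e-12). Within the low mouse numbers the difference was 1.14 and within the high ones 0.80. Without Control 1, Control 2, cKO 1 or cKO 3 in turn 2 members passed over the list alone, and without Control 3 and cKO 2 the counts were 7 and 4.

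**Figure D2:**
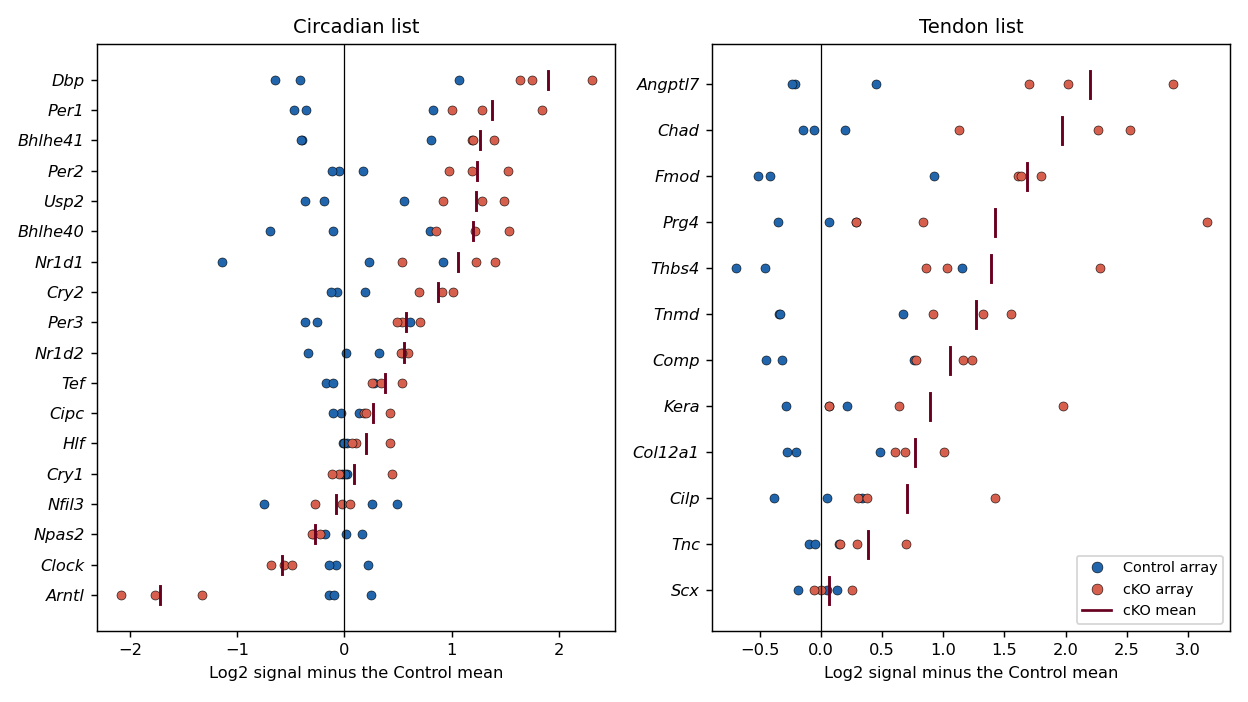
Log2 signal of each array minus the Control mean for the measured genes of the circadian list (left) and the tendon list (right), with Control arrays in blue, cKO arrays in orange and the cKO mean as a vertical bar. The cKO mean of Arntl lies at -1.73 and that of Dbp at 1.90, and all 12 tendon genes have a cKO mean above the Control mean.

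Markers of other cell types that could be in the dissected muscle did not pass as groups on the values as deposited, tendon apart, and some lists passed under an alternative. Connective tissue fibroblast genes differed by 0.27 log2 units (SE 0.28, camera adjusted p = 0.367), with Fn1 at 1.10 (SE 0.54) and Lum at -0.87 (SE 0.41), and by 0.44 within the low against -0.03 within the high numbers. Fibroblast array means were 8.06, 8.22 and 8.57 in Control 1 to 3 and 8.57, 8.13 and 8.95 in cKO 1 to 3. Smooth muscle and pericyte genes differed by 0.25 (SE 0.10, adjusted p = 0.0768, Mustn1 0.95, Cspg4 0.45) and adipocyte genes by 0.24 (SE 0.09, adjusted p = 0.0768), with the lipases Pnpla2 and Lipe at 1.01 (SE 0.27) and 0.55 (SE 0.20). The smooth muscle list passed with the number range as a block (adjusted p = 0.0423), with no filter (0.0203) and without Control 1, cKO 1 or cKO 2 (0.0122, 0.0267 and 0.0205), in a range of 0.0122 to 0.758. The adipocyte list passed after quantile normalization (adjusted p = 0.0191) and median centring (0.0466), after quantile normalization with the range block (0.0457), and without Control 1, cKO 1 or cKO 2 (0.00816, 0.0340 and 0.0104), in a range of 0.00816 to 0.741. Macrophage genes differed by 0.23 (SE 0.20, adjusted p = 0.208), with 20 of 21 higher, Itgam at 0.38 and Cd14 at -0.36. Without cKO 2 the fibroblast and macrophage lists passed (adjusted p = 0.0104 and 0.00468, in ranges of 0.0104 to 0.911 and 0.00468 to 0.830). Endothelial genes had a mean of -0.03 (SE 0.32) and a median of 0.02 (adjusted p = 0.132), with Sox18 at 0.64 and Cldn5 at -0.45. Their difference was -0.34 within the low and 0.56 within the high numbers, and the list passed, downward, with array weights (adjusted p = 0.0292) and without Control 3 or cKO 3 (8.29e-06 and 0.0128), in a range of 8.29e-06 to 0.956. Schwann cell genes had a mean of 0.05 (SE 0.10), which was -0.02 after quantile normalization, against a downward direction in camera (adjusted p = 0.861, Sox10 0.16, Pmp22 0.17). The erythroid list had 2 measured genes, Alas2 at -0.42 and Bpgm at 0.07 (adjusted p = 0.350, list means 0.09 within the low and -0.14 within the high numbers), and the lymphocyte list 1, Cd3d at 0.06 (SE 0.18, adjusted p = 0.949). Bone and osteocyte genes had 3 measured members and a mean of -0.06 (SE 0.14, adjusted p = 0.434), with Alpl at -0.34 and Bglap at 0.17, and list means of 0.04 and 0.03 within the low and high numbers. Dmp1 itself was below the filter. Over each of these lists alone limma passed 0 members, with up to 5 of a list at an unadjusted p under 0.05.

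Immediate early and heat shock genes, which respond within minutes to stress or stimulation, rose by a mean of 0.41 log2 units (SE 0.12) and a median of 0.23, with 17 of 21 members higher (14 after quantile normalization). Jun at 1.26 (SE 0.25), Myc at 0.79 (SE 0.19), Ier3 at 0.77 (SE 0.19) and the phosphatase gene Dusp1 at 1.28 (SE 0.34) passed 0.05 adjusted over the list alone in limma, and 0 passed over all features. The chaperone gene Hspa1a differed by 1.96 (SE 0.57), while Fos and Egr1, other early genes of the list, differed by -0.03 (SE 0.23) and 0.10 (SE 0.54). The list passed camera (adjusted p = 0.0453), and not with an estimated correlation (adjusted p = 0.741, the highest of 19 alternatives from 0.00497). The call was also lost without Control 2, Control 3 or cKO 2 (adjusted p = 0.0869, 0.332 and 0.127), with array weights (0.135) and with the stricter filter (0.140). The count of 4 members past 0.05 over the list alone was 1 after quantile normalization, 1 after median centring, 2 with the stricter filter, and 0 or 1 without any 1 array. The difference was 0.39 within the low and 0.57 within the high mouse numbers.

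By camera with its preset correlation, mitochondrial energy metabolism genes fell relative to other genes, by small amounts. Citric acid cycle genes had a mean difference of -0.16 log2 units (SE 0.10), with 10 of 16 lower, and those of the pyruvate dehydrogenase complex, Pdhb, Pdha1 and Dld, differed by -0.71 (SE 0.18), -0.34 (SE 0.17) and -0.44 (SE 0.25). Sucla2 differed by -0.44 (SE 0.22). Oxidative phosphorylation genes had a mean of -0.10 (SE 0.13), with 25 of 30 lower, Ndufs1 of complex I at -0.48 (SE 0.20), Cox7a1 and Cox5b of complex IV at -0.42 (SE 0.27) and -0.42 (SE 0.32), and Atp5d of the ATP synthase at 0.48 (SE 0.18). Fatty acid oxidation genes had a mean of -0.04 (SE 0.17), with 13 of 22 lower, Etfa at -0.54 (SE 0.21), Acadm at -0.38 (SE 0.16), Acadl at -0.25 (SE 0.17) and Lpl at -0.25 (SE 0.21), and Ppargc1a, a regulator of mitochondrial genes, differed by 0.24 (SE 0.95). Camera's adjusted p was 0.000745, 0.000745 and 0.0170 for the 3 lists, and with an estimated correlation adjusted p = 0.741, 0.758 and 0.793. Over 19 alternatives each, the adjusted p ranged from 0.000172 to 0.741, from 8.29e-06 to 0.758 and from 0.000219 to 0.797. Members past 0.05 over the list alone numbered 0 in limma for each list, with 1, 2 and 2 at an unadjusted p under 0.05. Within the high mouse numbers the mean differences were -0.06, 0.08 and 0.24, against -0.16, -0.15 and -0.21 within the low ones. The citric acid cycle call was lost without cKO 1 (adjusted p = 0.0806), and the mean was -0.09 without Control 2 and -0.11 with the number range as a block. For oxidative phosphorylation the mean was 0.01 without Control 2, where the call was lost, -0.20 without Control 3 and -0.04 without cKO 3. Its call was lost without cKO 1 as well (adjusted p = 0.1004), with array weights (0.128), and with quantile normalization and the range block together (0.0960), and its mean was -0.04 with the number range as a block and -0.16 after median centring. The fatty acid oxidation mean lay between -0.17 without Control 3 and 0.08 without Control 2, turned to 0.03 without cKO 3, to 0.03 with array weights and to 0.01 with the number range as a block, and was -0.13 without cKO 2 and -0.02 without cKO 1. Its call was lost without Control 1, Control 2 or cKO 1 (adjusted p = 0.150, 0.243 and 0.516), with array weights (0.269), after quantile normalization or median centring (0.139 and 0.0867, with means of -0.09 and -0.10), and with quantile normalization and the range block together (0.357).

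The remaining muscle lists did not pass on the values as deposited. Atrophy and proteolysis genes had a mean difference of 0.37 log2 units (SE 0.07, camera adjusted p = 0.186) and a median of 0.17, with 20 of 25 higher (16 after quantile normalization), metallothionein Mt2 at 3.77 (SE 1.06) and the autophagy receptor Sqstm1 at 0.82 (SE 0.25). The muscle ubiquitin ligases differed the other way, Fbxo32 at -0.61 (SE 0.22), with full separation of the groups, and Trim63 at -0.52 (SE 0.31). Calcium handling and excitation genes had a mean difference of 0.33 (SE 0.17, adjusted p = 0.367) and a median of 0.17, with Cacng1 at 1.74 (SE 0.54) and sarcolipin Sln, an inhibitor of the calcium pump, at 2.30 (SE 0.45). Shared sarcomere genes differed by 0.26 (SE 0.07, adjusted p = 0.0895), with Xirp1 at 1.66 (SE 0.22) and filamin C, Flnc, at 0.74 (SE 0.20). Sln and Xirp1 each passed 0.05 adjusted over their list alone in limma. The call of Sln was lost after quantile normalization and without Control 1, cKO 1, cKO 2 or cKO 3, while the sarcomere list had 1 member past in each of these settings. The calcium list differed by 0.51 within the low and -0.0036 within the high numbers, and passed with array weights (adjusted p = 0.0292) and without Control 3 (0.0199), in a range of 0.0199 to 0.940. The sarcomere list passed after quantile normalization (adjusted p = 0.00112), with no filter (0.0336), without a trend (0.0353), with array weights (0.000664) and without cKO 1 (0.00101), in a range of 0.000664 to 0.911. Growth factor genes differed by 0.16 (SE 0.07, adjusted p = 0.436), with follistatin, Fst, at 1.06 (SE 0.27), Igf1r at 0.44 (SE 0.15), myostatin, Mstn, at 0.07 (SE 0.27) and Igf1 at 0.08 (SE 0.18), whose sign turned under quantile normalization. Glycolysis and glycogen genes differed by 0.13 (SE 0.11, adjusted p = 0.501, Gys1 0.63, Slc2a4 0.49), fatty acid synthesis genes by 0.19 (SE 0.09, adjusted p = 0.474, Gpam 0.49, Scd1 1.21) and cell cycle genes by 0.19 (SE 0.08, adjusted p = 0.0830, Mcm6 0.41, Rrm2 0.48), the last with 9 of 9 higher. Of the cell cycle genes, 6 of 9 were higher after quantile normalization and 7 of 9 after median centring. Glycolysis array means were 13.50, 13.70 and 13.62 in Control 1 to 3 and 13.75, 13.88 and 13.57 in cKO 1 to 3. Glycolysis genes passed with array weights (adjusted p = 0.0314, in a range of 0.0314 to 0.911) and cell cycle genes without cKO 2 (0.0151, in a range of 0.0151 to 0.793). Interferon genes had a mean of -0.06 (SE 0.17) and a median of 0.05 (adjusted p = 0.499, Bst2 -1.45, Stat2 0.32), and differed by -0.0095 within the low and 0.08 within the high numbers. Notch1 differed by 0.04 (SE 0.16), with a sign that turned under both scalings. In the cholesterol and stress lists Nsdhl, Mvk, Asns and Xbp1 differed by 0.31, 0.29, 0.66 and 0.63.

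Among single genes, none of the 8 higher and 8 lower with the smallest p, full separation and a fold of at least 1.5 passed the adjusted threshold (limma adjusted p = 0.999 for each). Higher in cKO were the actin-binding Xirp1, the clock gene Per2, the lipopolysaccharide receptor Tlr4 at 1.08 (SE 0.17), Angptl7, the intracellular channel protein gene Clic4 at 1.21 (SE 0.21), Chad, Abhd4 at 0.95 (SE 0.18) and the fibronectin receptor subunit Itga5 at 1.29 (SE 0.24). Lower in cKO were Lrtm1 at -2.05 (SE 0.26), Arntl, the insulin receptor adaptor Grb14 at -1.02 (SE 0.21), the mTORC1 inhibitor Ddit4l at -1.63 (SE 0.34), the homeobox gene Barx2 at -0.83 (SE 0.19), Rsl1 at -0.76 (SE 0.19), the tubulin chaperone Tbca at -0.95 (SE 0.24) and Pdhb. An exact permutation test of any of these genes alone gives p = 0.1, the smallest that 3 against 3 arrays allow. Of the 223 features in the second count, 116 carried a named gene, 34 a predicted gene or small RNA, and 73 several symbols or none. Without Control 3, Fmod passed the adjusted threshold at 2.15 log2 units (limma adjusted p = 0.0364).

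**Figure D3:**
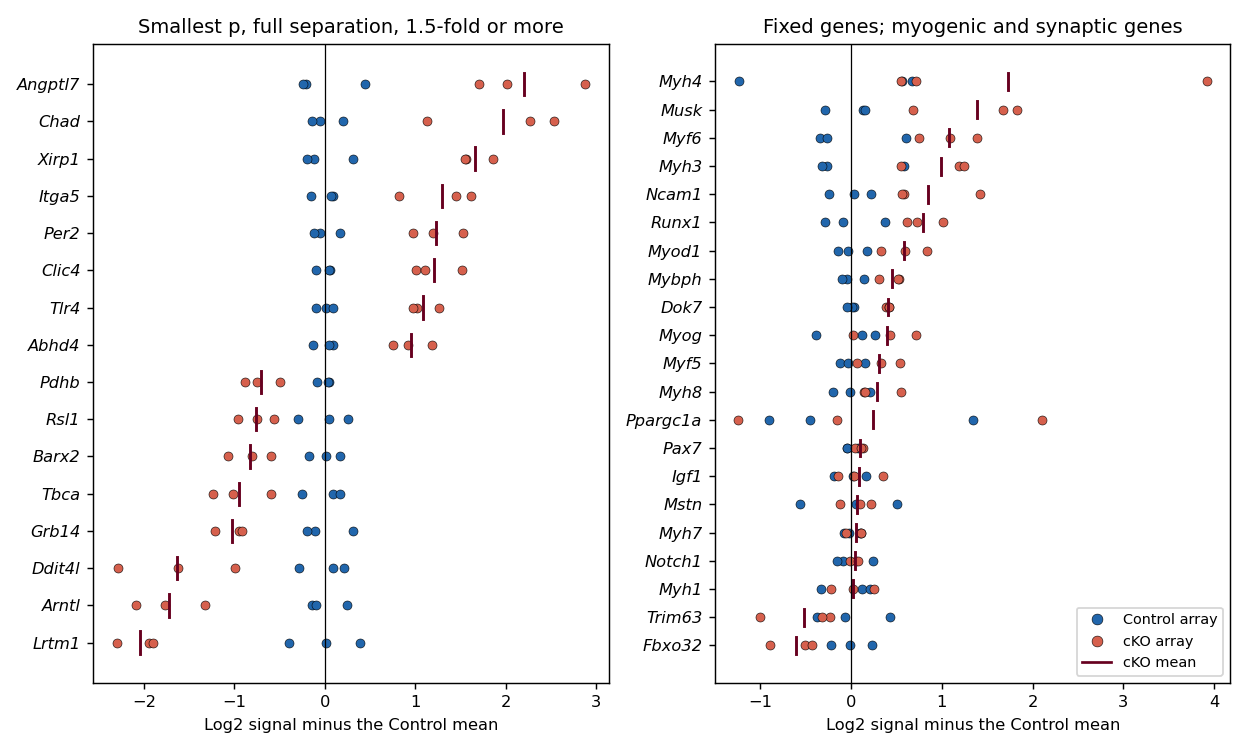
Log2 signal of each array minus the Control mean for the 8 higher and 8 lower genes with the smallest p (left) and for fixed muscle genes with the named myogenic and synaptic genes (right), with Control arrays in blue, cKO arrays in orange and the cKO mean as a vertical bar. The cKO mean of Lrtm1 lies at -2.05 and that of Angptl7 at 2.20, with no overlap of the groups for any gene on the left.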

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

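Tests without saturated features, and with quantile normalization and the number range together as a block, were chosen after the results were seen, and their counts lie within the ranges below. Over 1764 comparisons of single genes with an alternative 1 gained a call and 36 changed sign uncalled, which does not speak for stability, since no gene was near the threshold. Robust eBayes and single-symbol features left every list value as it was. Over the other 569 comparisons of lists 484 kept the sign of the mean and the side of the threshold, 20 changed sign uncalled, 32 lost a call and 27 gained one. In the other 6 the mean turned sign with a call on either side. A turned mean is not a turned camera direction, which is relative to all other genes. The count of 223 features became 130 with median centring, 823 with array weights and 94 at a fold of 2, and lay between 94 and 944 without 1 array. The limma count of 0 features past the adjusted threshold lay between 0 and 14, the 14 arising without Control 3. The 21 list members past 0.05 over their list alone became 55 with array weights, and lay between 6 (without Control 1 or cKO 3) and 35 (without Control 3). The 8 lists became 0 with an estimated correlation and 0 with fry, and 5 to 14 without 1 array, 5 without Control 2 and 14 without cKO 2. The myogenic list kept its mean of 0.484 with an estimated correlation and with fry, which change only the test, at adjusted p of 0.741 and 0.194 in a range from 6.60e-07. The fast fibre mean ran from -0.056 without cKO 2 to 0.591 without cKO 3. The fatty acid oxidation mean turned to 0.032 with array weights and 0.0144 with the number range as a block, and ran from -0.167 to 0.0838 without 1 array. The oxidative phosphorylation mean ran from -0.200 to 0.00728. With 5 arrays fewer degrees of freedom remain, and otherwise the cause was not tested. The lymphocyte list gave no value under the stricter filter, which left it no gene.

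Replicate numbers did not pair the samples: same-numbered arrays deviated from their group means with correlations of 0.128, -0.204 and 0.205, so not every array tracked its own number. With the replicate number as a block the second count was 217, features past the adjusted threshold 0, lists 9 and list members 20. The macrophage list passed (adjusted p = 0.0390, in a range of 0.00468 to 0.830), and no immediate early member passed over the list alone. Features near the array median carry little signal over background, which limits satellite cell, lymphocyte and bone genes. The same limit holds for Mybph (4.17, 4.11 and 4.36 in Control 1 to 3), Ier3 (4.05, 4.02 and 4.22) and Myod1 (4.61, 4.72 and 4.93). The Control medians were 4.13, 4.03 and 4.08. The median was highest on cKO 1, at 4.37, where Mybph and Myod1, but not Ier3, were highest as well. The 40 saturated features give no fold as single genes.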

Other observations

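Tests of the clock, the tendon list and the splits of the arrays were chosen after those results were seen. Tests of glucocorticoid targets and of the neighbours of Mbtps1 were stated before their set values were computed, but their single genes had been fitted. The targets Fkbp5, Tsc22d3, Klf15 and Cebpd also belonged to the atrophy and proteolysis list. Clock genes whose RNA peaks at opposite times of day were taken as 2 sets. The evening set (Per1, Per2, Per3, Dbp, Tef, Hlf, Nr1d1, Nr1d2, Bhlhe41 and Usp2) was 0.98 log2 units higher in cKO (SE 0.18), and the morning set (Arntl, Npas2, Clock and Nfil3) was 0.66 lower (-0.66, SE 0.14). Arntl and Clock, at -1.73 and -0.58, carried the morning mean, against -0.27 for Npas2 and -0.08 for Nfil3. Each comparison had an exact permutation p of 0.1, the smallest possible. The evening minus morning score was -0.44, -0.28 and 0.49 in Control 1 to 3 and 1.36, 1.53 and 1.81 in cKO 1 to 3. Control 3, the high-numbered Control mouse, lay nearest to the cKO mice.

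For the clock pattern, array scaling alone would move both sets one way. After quantile normalization the morning set was still lower, at -0.761 (SE 0.18), so this scaling did not remove the difference. The test cannot exclude scaling, because the sets were drawn up after the values were seen. The morning set holds the 4 lower members of the clock list. With the number range in a linear model, the evening minus morning difference was 1.448 over all 6 arrays (SE 0.19, 95% interval 0.84 to 2.06, 3 residual degrees of freedom). It was computed on the same sets, so it gives the size left with the range in the model and does not exclude the range. Within the high and the low numbers it was 1.18 and 1.72, each with a single array of one genotype. A shift in phase needs the sets to differ oppositely, but that is the pattern that prompted the test, so their difference of 1.641 (SE 0.31) gives only its size and decides nothing. A phase shift, from genotype or from a time of dissection that no label gave, stays open and untested.

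For the tendon list, a difference of 0.971 remained with the number range in the same model (SE 0.18, 95% interval 0.40 to 1.54, 3 residual degrees of freedom). This test was chosen after the list was seen to have the highest mean of the 30, so it does not exclude the range. The values of 0.80 and 1.14 within the high and low numbers each rest on a single array of one genotype. A candidate explanation is more tendon tissue in the cKO pieces. Of the 14 listed genes 12 passed the filter, which takes no account of group, and no other list holds them. Of 6 abundant tendon matrix genes outside the list, 5 of them also in the fibroblast list, Col1a1, Col1a2, Bgn and Sparc differed by 0.86, 0.72, 0.68 and 0.59, and Dcn and Lum by -0.23 and -0.87. Their mean difference of 0.2925 (SE 0.35, exact permutation p = 0.6) leaves tendon tissue and a change within the muscle open, because its spread covers both 0 and a clear rise. Dcn had the highest signal of these genes, at 13.8 to 15.1 on the 6 arrays, but signals of different features do not rank abundance.

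Jun and Dusp1 passed over their list alone. Mt2 did not, and stood at 9.30 in cKO 1 against 13.0 and 13.2 in cKO 2 and cKO 3. Glucocorticoid exposure at killing was tested on 9 other targets, a 10th chosen gene, Glul, having no single-symbol feature. Their mean difference of 0.1296 (SE 0.15, exact permutation p = 0.5) neither exceeded 2 standard errors nor excluded the 0.41 of the immediate early list, so exposure could not be decided. A genotype effect stays untested beside it.

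Of the 50 tested genes nearest to Mbtps1, 11 had full separation of the groups, all 11 higher in cKO. This was 22% (95% exact Clopper-Pearson interval 11.5% to 36.0%), against 14.1% of all tested genes (one-sided Fisher's exact test p = 0.0851), which left open whether DNA linked to the targeted allele differed. The shared direction is not particular to these genes. Of the 1501 features with an unadjusted p under 0.05 in limma, 1232 were higher in cKO.

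The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For features past the adjusted threshold the real count was 0, the highest other split 1, and 10 splits were as large. For the second count the real value was 223 and the highest other 1155, which came from the split by mouse number range, and 3 splits were as large. The count with the range as a block was 265. That split's count, several times the real one, points to a structure of the samples along the numbers, and 4511 features had an unadjusted p under 0.05 for the range in limma, with 0 past the adjusted threshold. For gene lists the real count was 8, the highest other 13, again the range split among them, and 5 splits were as large. For list members past 0.05 over their list alone the real count was 21, the highest other 4, and only the real split, 1 of 10, was as large.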
